A study of Mus musculus with 10 samples.

How the data were processed

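Gene expression was measured in mouse aortic arch on 10 two-colour arrays. Per the labels, RNA was amplified with T7 polymerase (MessageAmp), labelled chemically (Micromax ASAP) and hybridised with 1 genotype in each channel. Slides were read on a GenePix 4000B scanner with GenePix Pro 3.0 and analysed in GeneSpring, per the labels' descriptions. The deposited values are log2 ratios of the channels, which the authors give as apoE-null over double-null for every array, per the titles. The normalization method, the reason for blank cells and the array layout are not given in the sources used here. Scanner intensities were not analysed here, so signal over background is unknown and the number of arrays and blank cells limits the precision.

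Between 49.1% and 67.0% of the cells of an array were blank. The lowest value, -6.64, is the log2 of 0.01 and occurs 10 times on 5 arrays, which fixed the base of the logarithm and points to a floor. Deposited array medians lay between -0.01 and 0.09, within 0.1 of 0, so the deposited normalization was kept. No column of values was left unused.

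Signs were turned so that all ratios read double-null over apoE-null. The direction from the titles was checked in 3 ways: the partner arrays of each pair correlated above 0 across probes (Pearson's r of 0.56, 0.31, 0.04, 0.19 and 0.46 in pairs 1 to 5, against -0.32 to 0.15 for arrays of different pairs and orientations, so that the value of pair 3 alone decides nothing), Myd88 was below 0 on all arrays, and Xist and Eif2s3y followed the sexes in pair 5, whereas Kdm5d, with a value on 1 of its arrays, did not separate them. After each orientation's mean was removed from each probe, the partner correlations were between 0.43 and 0.72, over probes with values on at least 8 arrays. These are correlations across probes, which are not independent replicates. The 2 arrays of pair 1 name the same mice with genotypes exchanged; the genotype labels were used.

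The 2 arrays of a pair hold the same RNA extracts and were averaged to 1 replicate. A pair value needed both arrays, and a probe needed 3 pair values: 3612 probes had 5, 838 had 4 and 416 had 3. The labels number separate mice, so p-values measure the spread between mouse pairs. Each probe was tested against 0 with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05; an adjusted p for a gene comes from this fit or, for list members, from the same fit over 4299 genes with their probes averaged. A dye effect was tested in the same way on the difference between the orientations of each pair, divided by 2, and 231 of 4866 probes had one.

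Gene names came from the platform annotation, updated by Entrez identifier through the RefSeq annotation of assembly GRCm38.p6, which was used only for names and gene order. Of the probes, 12143 had 1 gene symbol, 49 had several and 1680 had none; 12009 of the single symbols matched by identifier and 134 kept the older name. Genome coordinates are not given because no build is named by the files.

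For gene lists, probes of a gene were averaged, which left 4299 genes. From 27 lists, 22 with at least 5 measured genes were tested with limma's camera (preset inter-gene correlation 0.01, from moderated statistics), again with an estimated correlation, and with fry. The last 2 cannot take missing values and used genes measured in all 5 pairs. Camera with an estimated correlation also takes its degrees of freedom from the pairs, and with the preset one from all genes. The 2 camera settings therefore differ in more than the correlation. Fry tests whether the genes of a list move one way on balance, and called no list; its smallest adjusted p was 0.0705, for chemokines and MHC class II. The list medians, means and tests differ in sign for the B cell, oxidative stress, cholesterol synthesis and endothelial lists, none of which passed.

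The lists, tests, filters and most alternatives were fixed before the data were examined, as was the rule for naming genes. It takes Myd88 and Apoe, then among probes past the threshold with 1 proper gene symbol and 1 direction in every pair the 12 higher and 12 lower with the largest mean log2 ratio, and then up to 4 members with the smallest p of each list described. Other genes named in the text were chosen after their values were seen; these are Ppbp, Serpina1d, Serpina1e and Spi1-6, the erythroid genes beside Hba-ps3, and those in the closing section. Alternatives were leaving out each pair, array-level fits, single orientations, other empirical Bayes settings, centring, scaling, filters, the male pairs alone and a looser threshold. Added after the data were seen were leaving out probes with a dye effect, centring within 48 runs of consecutive probe identifiers, removing floor values, an adipocyte covariate and the estimated correlation as a setting.

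The fit was tested on simulated data with 4866 genes of which 200 were changed, in 10 simulations of the comparison of double-null over apoE-null. It recovered 80.1% of genes changed by 1 on the log2 scale and 96.2% of those changed by 2, with 4.54% false calls. Camera called 20 of 20 simulated lists shifted by 0.5 and 0 of 400 unshifted lists. All these simulations had independent genes and no dye effect. They therefore do not give the share of false calls among real probes that have a dye effect.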

Results

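RNA from the aortic arch of mice lacking both apolipoprotein E and MyD88 (double-null) was compared with RNA from mice lacking apolipoprotein E alone (apoE-null) on 10 two-colour arrays. Loss of apolipoprotein E, a ligand that clears lipoproteins from blood, raises plasma cholesterol and gives mice atherosclerotic plaques. MyD88 is the adaptor protein that carries signals from the interleukin-1 receptor family and most Toll-like receptors. By its title the series concerns reduced atherosclerosis in mice without MyD88, and the comparison asks how the transcripts of the diseased vessel differ between the genotypes. The labels of 8 arrays state a high fat diet for 8 weeks. Arrays without this statement hold the same mice as arrays that have it. Each array held 1 mouse of each genotype, and each of 5 mouse pairs was hybridised in both dye orientations, so the number of replicates is 5. Pair 1 was female, pairs 2, 3 and 4 were male, and pair 5 set a male double-null mouse against a female apoE-null mouse. Each array gave between 4581 and 7057 values for 13872 probes, and 4866 probes had values on both arrays of at least 3 pairs. Ratios are given here as double-null over apoE-null, the opposite of the deposited direction, so a negative log2 value means less transcript in double-null mice.

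The disrupted gene was lower in double-null aorta in every pair. Myd88 fell 1.86-fold, with a log2 ratio of -0.90 ± 0.22 (SD, n = 5 pairs, adjusted p = 0.0248), and its ratio was below 0 on all 10 arrays. Whether the Myd88 probe lies in the disrupted part of the gene is not given in the sources used here. Apoe, disrupted in both genotypes, had a log2 ratio of -0.36 ± 0.15 (SD, n = 3 pairs) that did not pass the test (adjusted p = 0.511). In the pair of unlike sex, Xist, expressed from the inactive X chromosome of females, had log2 ratios of -3.54 and -4.26 on the 2 arrays, and the Y-linked Eif2s3y had 1.93 and 2.63, as the sexes in the labels require. The Y-linked Kdm5d, with a value on 1 array of that pair, read 0.20 there against 0.33 to 0.75 on arrays of male pairs and did not separate the sexes.

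The chemokine genes Cxcl1, Ccl7 and Ccl2 were lower in double-null aorta. Cxcl1, a neutrophil attractant, fell 3.17-fold, with a log2 ratio of -1.67 ± 0.47 (SD, n = 5 pairs, adjusted p = 0.0122) and a decrease in 5 of 5 pairs. Ccl7, a monocyte attractant, fell 3.05-fold (log2 -1.61 ± 0.35, SD, n = 4 pairs, adjusted p = 0.0165). Ccl2, the main ligand of the monocyte receptor Ccr2, fell 2.05-fold (log2 -1.04 ± 0.49, SD, n = 5 pairs), with an adjusted p of 0.0490 over 4299 genes and 0.0517 over all probes. Ccl8 had a log2 ratio of -1.57 ± 0.92 (SD, n = 4 pairs) and did not pass over all genes (adjusted p = 0.107). Of 18 chemokines measured, 3 fell, none rose and 15 did not pass. Adjusted over the list alone, 5 fell and 1 rose, the platelet chemokine Ppbp (log2 2.25 ± 1.99, SD, n = 3 pairs, adjusted p = 0.345 over all genes). The median log2 ratio of the list was -0.34 and lay below 0 in all 5 pairs, between -0.61 and -0.04. Camera called the list lower (adjusted p = 0.00274). With an estimated correlation, run on the 8 members measured in all 5 pairs, the call was lost (adjusted p = 0.637, unadjusted p = 0.0579). The estimate, 0.021, was near the preset 0.01, at which camera kept the call on these 8 genes (adjusted p = 0.0203). The settings also differ in their degrees of freedom, so the loss cannot be credited to the correlation alone.

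Outside the chemokine and MHC class II lists, 3 named genes fell besides Myd88. Cd5l, a secreted protein made by tissue macrophages that inhibits their apoptosis, had the largest decrease of any named gene, 4.07-fold (log2 -2.02 ± 0.62, SD, n = 5 pairs, adjusted p = 0.0122). Lcn2, an iron-siderophore binding protein induced by interleukin-1 and Toll-like receptor ligands, fell 2.38-fold (log2 -1.25 ± 0.26, SD, n = 3 pairs, adjusted p = 0.0439). Ear3, an eosinophil-associated ribonuclease, fell 2.23-fold (log2 -1.16 ± 0.17, SD, n = 4 pairs, adjusted p = 0.0217). The Ear genes are close paralogs, so the probe may not tell them apart. The Ear3 ratio also differed between dye orientations, with means of -0.65 and -1.57. In the list of inflammatory cytokines and mediators, 1 of 10 measured genes rose (Ltb, with log2 means of -1.01 and 2.69 in the 2 orientations), 1 fell (Lcn2) and 8 did not pass. S100a9 had a log2 ratio of 0.34 ± 0.60 (SD, n = 3 pairs) and Il1rn 0.30 ± 0.70 (SD, n = 5 pairs), and camera did not call the list (adjusted p = 0.307).

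Genes of MHC class II antigen presentation had a list median below 0 in 5 of 5 pairs, and macrophage genes in 4 of 5. All 5 measured MHC class II genes had negative log2 ratios, with a median of -0.71 and pair medians from -1.14 to -0.37. H2-DMa, which loads peptides onto class II molecules, fell 1.53-fold (log2 -0.62 ± 0.13, SD, n = 5 pairs, adjusted p = 0.0485). Cd74, the invariant chain, had a log2 ratio of -0.87 ± 0.40 (adjusted p = 0.0536), H2-Eb1 -0.71 ± 0.29 (adjusted p = 0.0640) and H2-Ab1 -0.75 ± 0.57 (adjusted p = 0.239), each SD with n = 5 pairs. Over all genes 1 of the 5 fell, and adjusted over the list alone 5 did. Of 38 macrophage and foam cell markers, 36 had negative ratios, with a list median of -0.42. None passed over all genes, and 5 fell adjusted over the list alone. The lysozyme genes Lyz2 and Lyz1, which are close paralogs, had log2 ratios of -0.81 ± 0.54 and -0.83 ± 0.60 (SD, n = 5 pairs), the C-type lectin Clec4n -0.89 ± 0.54 (SD, n = 4 pairs) and the complement gene C1qa -0.87 ± 0.41 (SD, n = 3 pairs). Macrophage pair medians were -1.09, -0.33, -0.67 and -0.32 in pairs 1 to 4 and 0.33 in pair 5, the pair of unlike sex. Camera called both lists lower, at adjusted p = 2.32e-06 for MHC class II and 2.79e-09 for macrophages. With an estimated correlation, which also lowers the degrees of freedom, neither call held, at adjusted p = 0.637 and adjusted p = 0.726. Fry called neither list, at adjusted p = 0.0705 for MHC class II and 0.584 for macrophages.

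**Figure D1:**
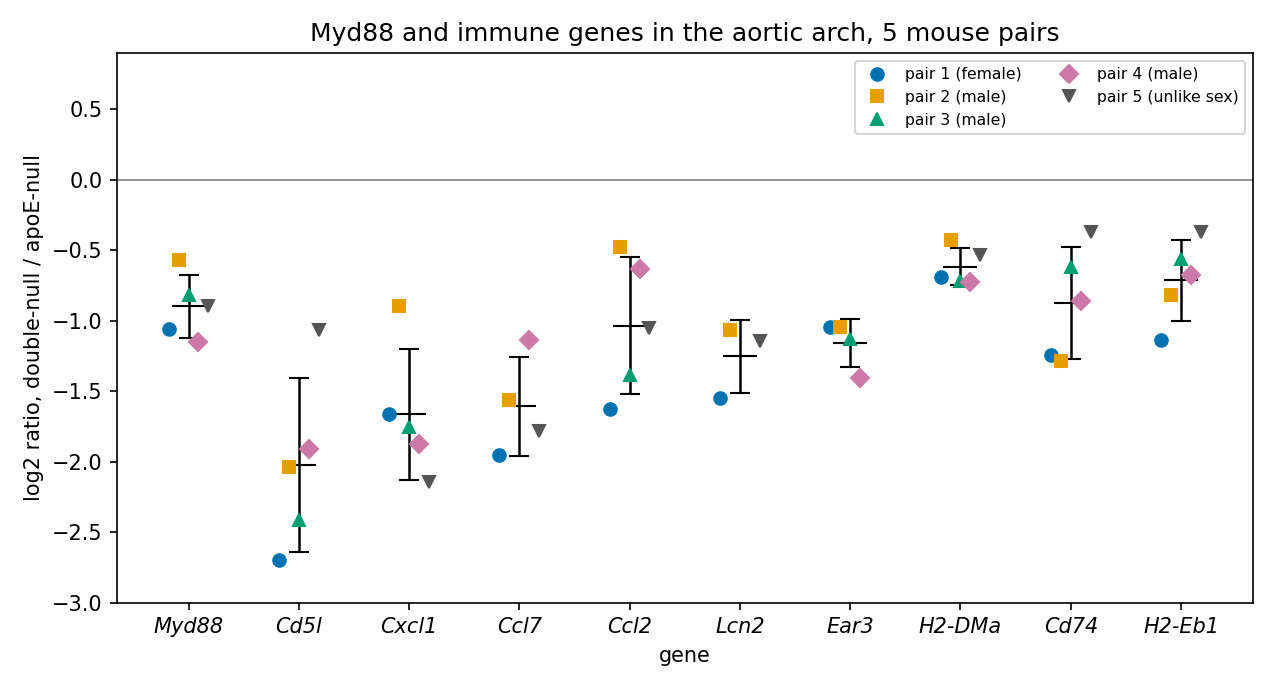
The log2 ratio of double-null over apoE-null aorta (vertical axis) is plotted for 10 genes (horizontal axis), with 1 symbol per mouse pair and a bar at the mean ± SD over the pairs with a value. Every plotted pair value lies below 0, which the naming rule required of Cd5l, Cxcl1, Ccl7, Lcn2, Ear3 and H2-DMa. H2-Ab1, not plotted, was at 0.11 in pair 5. Cd74 and H2-Eb1 did not pass the test over all genes (adjusted p = 0.0536 and 0.0640).

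Camera called mitochondrial and fat-related genes higher as groups in double-null aorta, but the pairs differed in direction. The oxidative phosphorylation median was above 0 in 3 of 5 pairs, and those of fatty acid oxidation and adipocyte markers in 2 of 5. Of 47 oxidative phosphorylation genes, 45 had positive ratios, with a list median of 0.29. Of 17 fatty acid oxidation genes, 15 did, with a median of 0.38. Of 16 adipocyte markers, 15 did, with a median of 0.51. No member of these lists passed, over all genes or adjusted over the list alone. The complex IV subunit Cox6b1 had a log2 ratio of 0.51 ± 0.62, the fatty acid oxidation enzyme Hadh 0.72 ± 0.87 and the adipokine Adipoq 0.65 ± 1.19 (SD, n = 5 pairs). Lpl, the adipocyte marker with the smallest p, went the other way at -0.42 ± 0.58 (SD, n = 5 pairs). So did Cpt1a in the fatty acid oxidation list, at -0.28 ± 0.38 (SD, n = 5 pairs). The adipocyte markers had pair medians of 2.30 in pair 1 and 0.97 in pair 4, against -0.36, -0.59 and -0.38 in pairs 2, 3 and 5. Fatty acid oxidation followed with 1.49 and 0.87 in pairs 1 and 4, against -0.17, -0.21 and -0.22, and oxidative phosphorylation had 1.19, 0.42, 0.11, -0.22 and -0.02 in pairs 1, 4, 2, 3 and 5. Extracellular matrix genes had 29 of 34 ratios negative, a list median of -0.19 and none passing over all genes or adjusted over the list alone. Their pair median was below 0 in 4 of 5 pairs and 0.22 in pair 3. The small proteoglycan Lum had a log2 ratio of -0.69 ± 0.44 (SD, n = 5 pairs) and the stromelysin Mmp3 -0.52 ± 0.42 (SD, n = 4 pairs). Camera called oxidative phosphorylation (adjusted p = 2.79e-09), fatty acid oxidation (adjusted p = 0.00274), adipocyte markers (adjusted p = 0.00343) and extracellular matrix (adjusted p = 0.00294). With an estimated correlation none held, at adjusted p = 0.726 for the first 3 and adjusted p = 0.760 for extracellular matrix. Fry called none of these lists, each at adjusted p = 0.584. Without pair 1 the oxidative phosphorylation median was 0.057, and the list was still called, and the calls of fatty acid oxidation (0.0092), adipocyte markers (-0.0025) and extracellular matrix (-0.08) were lost; the first 2 of these were also lost without pair 4 (0.25 and 0.25), and extracellular matrix without pair 5 (-0.14). In the 3 male pairs alone the medians of these 3 lists were 0.076, 0.080 and 0.030 and none was called, while oxidative phosphorylation, at 0.10, was.

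**Figure D2:**
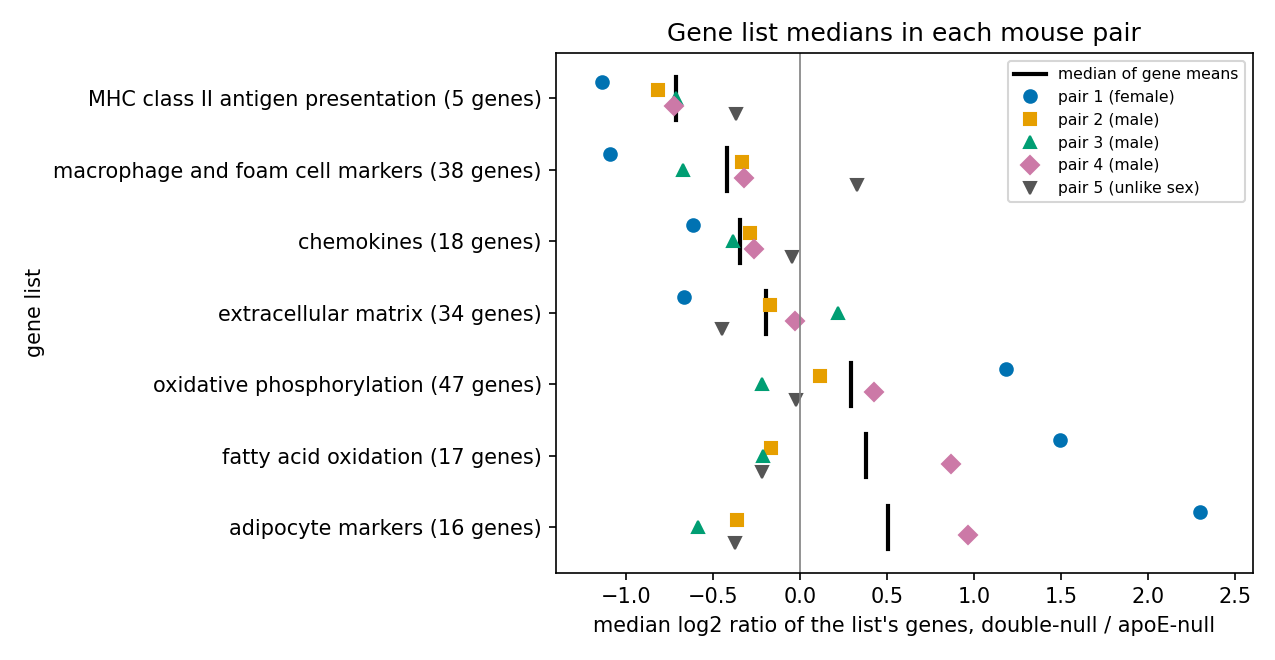
The median log2 ratio of each gene list (horizontal axis, double-null over apoE-null) is plotted for the 7 lists that camera called, with 1 symbol per mouse pair and a black line at the median over the genes' mean ratios. MHC class II and chemokine medians lie below 0 in all 5 pairs, whereas the adipocyte median is 2.30 in pair 1, 0.97 in pair 4 and below 0 in the other pairs.

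Probes called higher in double-null aorta were more numerous, and most of them carried a dye effect. Of 29 such probes, 22 had mean ratios of opposite sign in the 2 dye orientations, against 41.2% of all tested probes (Fisher's exact test, two-sided, p = 0.000198), and 24 had a dye effect at adjusted p under 0.05. Their median was -0.55 on arrays with double-null RNA in channel 1 and 2.29 on arrays with it in channel 2. Ptgfrn, an inhibitor of prostaglandin F2α receptor binding, had a log2 ratio of 1.43 ± 0.16 (SD, n = 5 pairs, adjusted p = 0.00480), with means of -1.06 and 3.93 in the 2 orientations. A second Ptgfrn probe had 0.85 ± 0.55 (SD, n = 4 pairs), did not pass (adjusted p = 0.203) and had means of -0.22 and 1.91. The endosomal sorting gene Vps25 had 1.43 ± 0.33 (SD, n = 5 pairs), with means of -1.42 and 4.28. The same opposition held for the named genes Mapk8ip2 (2.40, n = 3 pairs), Fndc4 (1.05), Pomk (1.02), Hmgb3 (0.99), Tcf15 (0.97), F10 (0.96) and Mapk8ip1 (0.96). Dsc2, a desmosomal cadherin, was positive in both orientations, with means of 0.39 and 1.90, but also had a dye effect.

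Among the genes named by the rule fixed in advance, those that rose without a dye effect were Serpina1a and Hba-ps3. Serpina1a, an α1-antitrypsin gene, rose 1.99-fold (log2 0.99 ± 0.30, SD, n = 5 pairs, adjusted p = 0.0252). The probes for its close relatives Serpina1e and Spi1-6 rose by 0.77 and 0.87 on the log2 scale, and as these genes are nearly identical their signals may not be separate, although the Serpina1d probe had a log2 ratio of -0.05. The α-globin pseudogene probe Hba-ps3 rose 1.95-fold (log2 0.96 ± 0.31, SD, n = 5 pairs, adjusted p = 0.0263), and globin genes share sequence with it. Its pair values differed from those of the Serpina1a probe by at most 0.12, although the genes are unrelated. Whether these 2 probes read separate transcripts was not tested. The erythroid genes Alas2, with a log2 ratio of 1.19 ± 0.78, and Hba-a1, with 0.46 ± 0.33, were also positive in 5 of 5 pairs (SD, n = 5 pairs) and did not pass over all genes (adjusted p = 0.118 and 0.318).

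**Figure D3:**
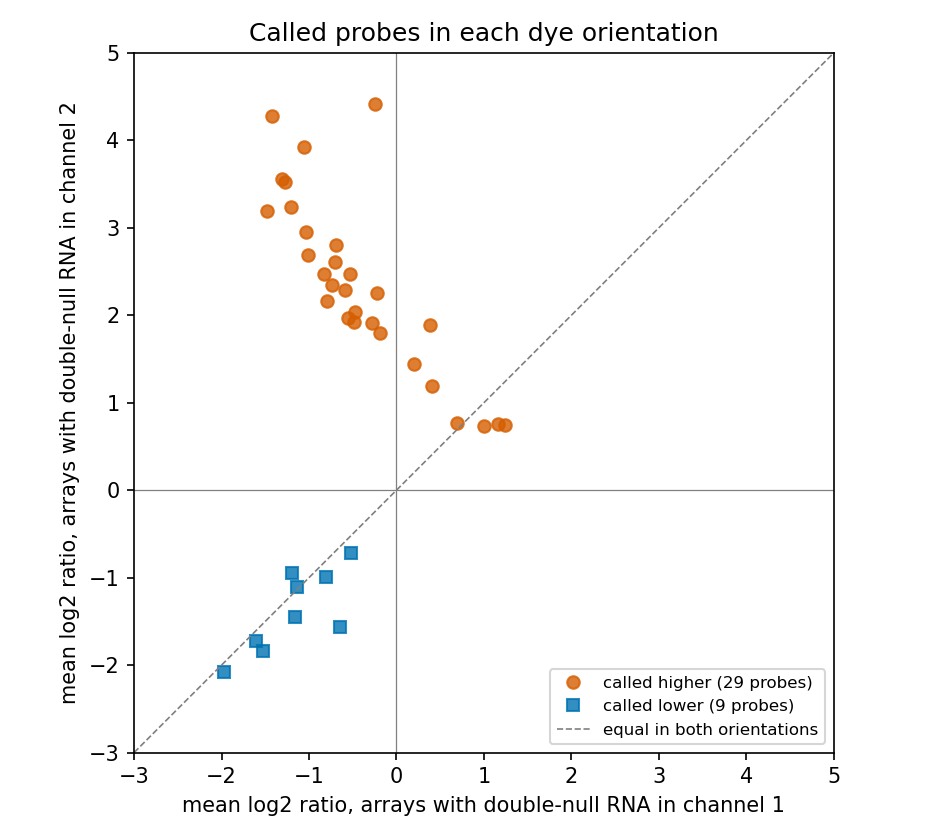
Mean log2 ratios of double-null over apoE-null aorta are plotted for the 38 called probes, on arrays with double-null RNA in channel 1 (horizontal axis) and in channel 2 (vertical axis), with a dashed line where both are equal. The 9 probes called lower are negative in both orientations, whereas 22 of the 29 called higher lie in the upper left, negative in one orientation and positive in the other.

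In all, limma called 38 of 4866 probes, 29 higher and 9 lower. None of the 9 lower probes changed sign between orientations, 1 of them (Ear3) had a dye effect, and 2 of them have no single gene symbol. At an unadjusted p under 0.05 there were 488 probes, 201 higher and 287 lower, and the median of all tested probes was -0.04. The count fell to 0 without pair 4 and to 25 without pair 5, with 11, 2 and 5 calls without pairs 1, 2 and 3, and to 4, all lower, when probes with a dye effect were left out, a setting chosen after the data were seen. Probes that stayed in that fit kept their log2 ratios, and Myd88, Serpina1a and Hba-ps3, without a dye effect, went to adjusted p = 0.0617. Camera called 7 of 22 lists with the preset correlation and 0 with an estimated one, where 1 list had an unadjusted p under 0.05. Of the 16 exchanges of genotype within pairs, the real one included, 12 gave 7 or more lists. An exact sign-flip permutation test over 5 pairs cannot go below p = 0.0625 (two-sided). On pair medians, this exact sign-flip permutation test gave p = 0.0625 for chemokines, MHC class II and proliferation, which camera did not call. The exact sign-flip permutation test gave p = 0.1875 for macrophage markers, 0.3125 for extracellular matrix and 0.375 for oxidative phosphorylation. The exact sign-flip permutation test gave p = 0.5 for fatty acid oxidation and 0.5625 for adipocyte markers.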

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

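The tests of dye effects, adipose tissue and glucocorticoid-induced genes were chosen after the results were seen; the exchanges of genotype within pairs were planned. The dye test on uncalled probes replaced one on sign changes and was fixed after its own outcome and other forms of it had been looked at. The test on the signs of array values was also fixed with its counts known, and the bounds of the adipose covariate test were revised with its values known. Between the female pair and the 3 male pairs, limma found 10 of 3775 probes whose ratio differed at adjusted p under 0.05, and no gene named before this section was among them, although several, such as Ccl7, Lcn2 and Apoe, lacked a value in 1 or more of these pairs and were not tested. With 1 female pair, the spread comes from the male pairs alone and the female pair is assumed to vary like them, so the p-values say nothing of other females. Of the 16 exchanges of genotype within pairs, too few for a share under 0.05, 1 gave 38 probes, the real one, with 1 probe as the highest of the others. For the lists, 12 of the 16 gave 7 or more, with 12 lists as the highest of the others, so the count of 7 does not stand above the exchanges. The median of the proliferation list in pair 2, 0.36, stood apart from the other pairs, which lay between 0.0029 and 0.059. It was the only such case among 62 groups of 5 values, and chance flags about 1 in 20.

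Dye effects weigh differently on the called probes. A dye effect of equal size in both orientations cancels in the pair mean, but among uncalled probes with a dye effect, 81.9% of those higher with double-null RNA in channel 2 had a mean above 0 (median 0.35), against 45.6% of those lower with it (median -0.02; Fisher's exact test across probes, which are not independent, two-sided, p = 6.00e-08). The second group lies near the median of all tested probes, -0.04, so the excess is in 1 direction only, that of all 24 probes called higher with a dye effect; for these it is consistent with a dye effect of unequal size in the orientations, and a genotype difference stays open, as how much of each ratio is dye was not tested. The 9 probes called lower, a set not split by the dye test, had the opposite sign in 0 of 86 array values. This argues against dye as the whole cause for these 9, although Ear3 has a dye effect. The 5 called higher without a dye effect had the opposite sign in 1 of 49 array values, against 106 of 233 for the 24. The dye test itself split these 2 sets, which largely fixed that contrast, so it decides nothing for the 5. Exchanging genotypes within pairs cannot separate a remaining dye effect from genotype, because both keep their sign in every pair.

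Tissue composition may account for part of the list results. The macrophage and MHC class II lists were lower in both orientations, where the highest of the 4 medians was -0.36, and in 2 of the 3 pairs with lower adipocyte markers in the double-null sample over 75% of their members were lower too (82.5% in pair 2 and 100% in pair 3, but 23.1% in pair 5). These values argue against a dye effect and against dilution by adipose tissue as the whole cause, and fewer macrophages in the vessel or less transcript per macrophage remain open. Dilution by other tissue was not tested, and pair 2 had the highest cardiac and skeletal muscle median of the pairs (log2 0.93). With the adipocyte list mean as a covariate, the fatty acid oxidation median went from 0.38 to 0.03 (adjusted p = 0.407), as more adipose tissue in the double-null samples of pairs 1 and 4 would give, and the extracellular matrix median from -0.19 to -0.11, where it was no longer called (adjusted p = 0.152). The oxidative phosphorylation median went from 0.29 to 0.07 and camera with the preset correlation still called it (adjusted p = 0.00800); most of the median followed the covariate and the remainder kept the call at that setting only (with an estimated correlation, which called no list without the covariate either, adjusted p = 0.781), so adipose tissue and genotype cannot be told apart for that list.

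Of the probes that differed between the female and male pairs, Tsc22d3, Ddit4, Mt2 and Cdkn1a belong to genes induced by glucocorticoids or stress. Tsc22d3 had a log2 ratio of -1.84 in the female pair and a mean of 1.75 in the male pairs, Ddit4 -2.28 and 1.56, Mt2 -2.58 and 0.66, and Cdkn1a -1.42 and 1.07; in pair 5 these ratios were -1.24, -1.49, -2.51 and -2.20. From a list of 17 other glucocorticoid-induced genes, 7 were measured in these pairs, and all 7 had lower ratios in the female pair than in the male pairs. Their median difference was -0.89, against a lowest 5% point of -0.41 in 10000 random lists. Genes of a random list need not move together, so this point is too easily passed by genes that do. In the female pair Cebpb was at 0.18 and Glul at -0.05, and the others lay between -1.17 and -0.41. A difference in glucocorticoid signalling between the mice compared, from sex, handling or time of collection, is a candidate explanation, and as there was 1 female pair these cannot be separated. Pairs 1 and 5 are those with a female apoE-null mouse.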

How the results depend on the processing

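Leaving out dye-effect probes, centring within runs of probe identifiers, removing floor values, the adipocyte covariate and, as a setting, the estimated correlation were chosen after the data were seen. Without 1 pair, between 0 and 25 probes were called, between 0 and 9 higher and between 0 and 16 lower; without pair 4, limma called 0, with 325 at an unadjusted p under 0.05. The dye coefficient with a random pair block called 73 probes (48 higher, 25 lower), and 10 independent arrays 64 (19 higher, 45 lower). Arrays with double-null RNA in channel 1 alone called 44 (7 higher, 37 lower), and those with it in channel 2 alone 111 (96 higher, 15 lower). The unmoderated statistic called 0 probes, 0 higher and 0 lower, with 415 at an unadjusted p under 0.05. Pair 1 from its first array alone gave 3 calls, 0 higher and 3 lower; the male pairs alone gave 55 (26 higher, 29 lower), of which 23 were among the 38; a threshold of 0.10 gave 74 (52 higher, 22 lower). Without dye-effect probes 4 remained, 0 higher and 4 lower, all 4 among the 9 lower calls; Myd88, Serpina1a, Hba-ps3 (each at adjusted p = 0.0617), Lcn2 (0.119) and H2-DMa (0.137) kept their log2 ratios and lost the call. On arrays with double-null RNA in channel 1 alone, the ratio turned for Mapk8ip2 (-0.25), Ptgfrn (-1.06), Vps25 (-1.42), Fndc4 (-0.69), Pomk (-1.20), Hmgb3 (-0.22), Tcf15 (-0.54), F10 (-1.04), Mapk8ip1 (-0.70) and Ltb (-1.01), as their dye effect shows. The extracellular matrix median turned to 0.030 in the male pairs alone; the cause was not tested. Cxcl1 stayed past the threshold in 18 of 21 alternatives, Cd5l in 17 of 21, Ccl7 in 16 of 19, Myd88 and Serpina1a in 13 of 21, Hba-ps3 in 12 of 21, Ear3 in 12 of 19, Lcn2 in 8 of 15, Ccl2 in 7 of 21 and H2-DMa in 4 of 21, with no change of sign. The camera calls of chemokines, macrophage markers, MHC class II and oxidative phosphorylation were lost in 1 of 20 alternatives each, the estimated correlation, where 0 lists passed. The other 19 all kept the preset correlation of 0.01, so they did not test that setting. The estimated setting also changed the degrees of freedom, so it did not test the correlation alone. The estimated correlations of these lists were 0.021, 0.62, 0.44 and 0.71. The medians of these lists ranged from -0.55 to -0.15, from -0.61 to -0.28, from -0.81 to -0.61 and from 0.057 (without pair 1) to 0.41. Fatty acid oxidation was lost without pair 1 (median 0.0092) or pair 4 (0.25), adipocyte markers likewise (-0.0025 and 0.25), and extracellular matrix without pair 1 (-0.08) or pair 5 (-0.14). All 3 were lost in the male pairs alone and with the estimated correlation, and with the adipocyte covariate fatty acid oxidation (0.03) and extracellular matrix (-0.11) were lost. The inflammatory list, not called in the main fit, was called in 3 of 20 alternatives: without pair 1, in the male pairs alone and with the adipocyte covariate. With the covariate it was higher in double-null mice (median 0.14, camera adjusted p = 0.0318). Its pair medians were 0.29, 0.51 and 0.44 in pairs 2, 3 and 4, and -0.25 and -0.39 in pairs 1 and 5. A division into 48 runs of consecutive probe identifiers, possible print blocks, took between 1.37% and 15.8% of the variance of an array, most in pair 3; centring within them left 35 of the 38 calls. Signal over background is unknown, so its limit could not be judged.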

Other observations

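The comparison of Hba-ps3 with Serpina1a and of the further genes below was made after their values were seen; the test of genes near Myd88 was planned, but its repeat without dye-effect genes was added after its result was seen. The erythroid list had 3 measured genes, too few for a group test. None passed over all genes, and all 3 did adjusted over the list alone: Alas2, the heme synthesis enzyme of red cells (log2 1.19, adjusted p = 0.00535), Hba-a1 (0.46, adjusted p = 0.0176) and Car2 (1.34 ± 1.46, SD, n = 3 pairs, adjusted p = 0.0344 over the list alone and 0.495 over all genes), which was -0.19 in pair 3. The β-globin gene Hbb-b2 had a log2 ratio of 1.07 ± 0.75 (SD, n = 5 pairs). The pair values of the Hba-ps3 and Serpina1a probes, which belong to unrelated genes, differed by at most 0.12.

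Other groups gave no call in the main fit. The Toll-like and interleukin-1 receptor list, upstream and downstream of MyD88, had a median of -0.09 over 14 genes (adjusted p = 0.295), with Ly96 at -0.50 ± 0.44 (SD, n = 5 pairs) and Tlr2 at -0.47 ± 0.13 (SD, n = 3 pairs). Interferon response genes had a median of -0.07 over 20 genes (adjusted p = 0.554), and Isg20, at 1.06 ± 0.69 (SD, n = 5 pairs), was the 1 member that rose adjusted over the list alone. Smooth muscle contractile genes had a median of -0.15 over 18 genes (adjusted p = 0.295) and endothelial markers -0.01 over 21 (adjusted p = 0.554). Proliferation genes had positive medians in all 5 pairs (adjusted p = 0.0514) and were called in 12 of 20 alternatives, but their median was 0.29 (adjusted p = 0.000600) with double-null RNA in channel 1 and 0.026 (adjusted p = 0.964) with it in channel 2. Genes of lipid uptake and efflux had a median of -0.19 (adjusted p = 0.307). Cardiac and skeletal muscle markers had a median of 0.31 over 13 genes (adjusted p = 0.419). Their pair median was 0.93 in pair 2 and between -0.46 and 0.05 in the other pairs, with Mb at 2.74 in pair 2. Camera called this list in the male pairs alone.

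DNA of another strain flanking the disrupted locus could change genes near Myd88. Among the 50 annotated genes on each side, 6 were tested and 2 had an unadjusted p under 0.05 (Plcd1, log2 -0.32, and Ttc21a, log2 0.82), at the 95.6 percentile of 9026 random stretches with at least 5 tested genes. Neither passed over all genes, and Ttc21a had a dye effect; without it 1 of 5 genes remained, at the 83.3 percentile, so these data leave the question open.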
